A study of Mus musculus with 2 samples.

How the data were processed

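DNase-seq was measured in cerebellum from 2 female B6CASTF1/J mice at 36 days of age, 1 library each. The biosample labels name separate females but give both the same donor entry, so the spread between the replicates is taken as that between 2 animals only as far as those labels say. Replicate numbers are those of the labels.

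The authors deposited for each library a table of false discovery rates of the local cut rate, 2 peak lists and a list of footprints. The deposited listing of files gives mm10 as the assembly and the filtered alignments of the 1 library as the source, so peaks were called per replicate and not pooled. The aligner, the peak and footprint callers, their versions and their thresholds are not given in the sources used here. The deposited FDR file holds p-value-type numbers, false discovery rates from 0 to 0.05. The deposited peak lists give each peak a signal; its values were whole multiples of a step that differed between libraries (0.00479 and 0.00722), which fits a count scaled to sequencing depth, but no source states the scaling. Another column of the peak lists, where a summit is often given, held 75 in each row and was not used, so midpoints stood for summits. The deposited footprints carry the constant 0.01 and cannot be ranked.

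The longer peak list of each replicate was the main one, chosen before any result was computed. All of its peaks touched bases at an FDR of 0.05 or less, and 67.1% (replicate 1) and 64.7% (replicate 2) touched bases at 0.001 or less; all peaks of the shorter lists (92120 and 59409) did. Chromosomes 1 to 19, X and Y were used. Every peak ended within the chromosome lengths of the reference genome GRCm38.p6, the assembly that mm10 names. Coordinates are 1-based.

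Start sites were the 54361 distinct starts of protein-coding transcripts of protein-coding genes in GENCODE M21, in 21853 genes. A promoter peak lay within 1 kb of any start site of a gene, and the strongest was taken as its value. A distal peak lay over 1 kb from every such start site and was counted by its midpoint within 100 kb of the span of a gene's start sites. The promoter peaks of a gene in the 2 replicates need not overlap. A promoter peak can serve several neighbouring genes, and distal windows of neighbours overlap.

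The design, the 18 gene lists, the 30 consensus strings, the alternatives and the rule for named genes were fixed before the data were examined. The lists were granule cells, Purkinje cells, cerebellar inhibitory interneurons, Bergmann glia and astrocytes, oligodendrocyte lineage, microglia, endothelial and mural cells, choroid plexus and meninges, forebrain regulators and neurons, HOX genes, liver, striated muscle and heart, lymphoid and erythroid cells, germ cells, housekeeping genes, immediate early genes, GABA-A and NMDA receptor subunits, and Y-linked genes. The rule names the 4 members of each list with the strongest promoter peak in both replicates by mean percentile rank, and in 6 lists up to 4 members without one in both, in alphabetical order. It also names the 10 genes with most distal peaks by the lower count, the 10 strongest distal peaks by the lower percentile rank, the 5 strongest unshared peaks of each replicate, the 10 consensus sites with the highest ratio and those that did not pass. Some genes and 1 peak that the rule names are not used here.

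Peaks overlapping by at least 1 bp counted as shared, against 100 circular shifts of replicate 1 along each chromosome. Lists were compared with all other protein-coding genes by Fisher's exact test (two-sided), and distal counts with 10000 random lists matched by deciles on the number of genes within 500 kb (two-sided permutation), each with Benjamini-Hochberg adjustment over the 18 lists at 0.05. Consensus sites on either strand were counted in 150 bp windows at peak midpoints and in windows 1 kb to each side that touched no peak of either replicate. In footprints, widened by 5 bp per side, they were counted against windows of the same width in the same peak outside footprints, which could be placed for 88.7% and 95.2% of footprints inside peaks. Both used Fisher's exact test with adjustment over the 30 sites, and a site was called only if it passed in the same direction in both replicates. With a single group of 2 there was no test between groups of animals.

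The alternatives were reciprocal overlap of 50%, the stronger part of each list above its median, equal numbers of peaks, the shorter lists, start-site windows of 500 bp and 2.5 kb, a background matched on CpG ratio, distal windows of 50 kb, assignment to the nearest start site, no matching, 100 bp windows, GC-matched control windows, distal peaks only, other footprint widening and leaving out each replicate. GC-matched windows were drawn at random across the genome, touched no peak of either replicate and were not matched on place or repeat content. They could be found for 96.5% and 93.5% of peaks, and the rest were left out of that alternative.

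5 comparisons were tested on simulated data; peak strength, peaks near start sites, sites in footprints and densities on X and Y were not. For shared peaks, 60.5% of 20000 simulated peaks were planted as shared and 60.6% were recovered. Of gene lists planted at 95% accessible promoters among 21853 genes 83.3% were called, and of lists raised 2.5-fold in distal peaks 96.7%. A CTCF site planted in 10% of 20000 windows was found in 10.0%. Footprints moved at random inside their peaks overlapped by 43.4% where shifts gave 42.8%. The work used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, pysam 0.24.0 and matplotlib 3.10.9, and samtools 1.23.1.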

Results

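The data are DNase-seq libraries from the cerebellum of 2 female mice of the B6CASTF1/J strain, an F1 hybrid of C57BL/6J and CAST/EiJ, both 36 days old. DNase-seq maps open chromatin by sequencing the places where the enzyme DNase I cuts nuclear DNA, and a peak is a DNase I hypersensitive site. Each animal gave 1 library, called replicate 1 and replicate 2, and both belong to a single group, so no comparison between conditions was possible. Both libraries carry the same donor entry, so the animals are separate, and each SD a spread between animals, only as far as the biosample labels say. The questions taken up are which genes, sites and sequence elements were accessible in this tissue, and how far the 2 animals shared them. Replicate 1 had 140058 peaks covering 31.1 Mb and replicate 2 had 94426 peaks covering 20.8 Mb, both with a median width of 200 bp. The peak signals under 1 were whole multiples of a step, 0.00479 in replicate 1 and 0.00722 in replicate 2, for 100% of values to within 0.05 of a step. If a signal is a count scaled to depth, replicate 1 was 1.51 times as deep as replicate 2. The total counts themselves are not in the files used here. The signals are the authors' values, given here as signal units, and coordinates are in mm10. Genes and peaks are not replicates, so p-values taken over genes or peaks measure only the spread across them in these libraries.

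Markers of the most numerous cerebellar neurons lay in open chromatin in both animals. All 25 genes of the granule cell list, which marks the small excitatory neurons of the cerebellar cortex, had a peak within 1 kb of a transcription start site in both replicates, against 62.2% of the other protein-coding genes (adjusted p = 2.5e-05, Fisher's exact test, two-sided, Benjamini-Hochberg over 18 lists). The strongest were Tiam1, a Rac activator, at 14.2 ± 2.03 signal units (SD, n = 2), and Cbln3, a synaptic organiser of granule cells, at 12.02 ± 2.64. Neurod1, a neuronal bHLH factor, had 11.2 ± 3.03 and Zic2, a zinc finger factor, 9.35 ± 4.64 (SD, n = 2), or 6.07 without replicate 2. The peak of Cbln3 also lay within 1 kb of a start site of Khnyn. In replicate 1 these peaks lay on chromosome 16 at 90144141 to 90144380 for Tiam1, on chromosome 14 at 55884221 to 55884420 for Cbln3, on chromosome 2 at 79456561 to 79457000 for Neurod1 and on chromosome 14 at 122474941 to 122475520 for Zic2. Against genes matched on promoter CpG ratio, 100% of the granule list compared with 80.4% in random lists, and the list remained above (adjusted p = 0.0029, permutation).

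Of the 25 genes of the Purkinje cell list, which marks the large output neurons of the cortex, 21 had a promoter peak in both replicates (84.0%, adjusted exact p = 0.036). Icmt, a methyltransferase of prenylated proteins, had 13.6 ± 5.09 signal units, and Itpr1, the calcium release channel, had 9.23 ± 1.27 (SD, n = 2). Lhx1, a LIM homeodomain factor, had 7.30 ± 0.731. Pcp2, Ppp1r17 and Skor2 had no promoter peak in either replicate, and Gad1, which makes GABA, had a peak in replicate 1 alone at 0.9004. The call ended without replicate 1 (adjusted exact p = 0.055), with a 2.5 kb window (0.086), with the stronger peaks (0.42), with equal numbers of peaks (0.053) and against genes matched on CpG ratio, where random lists reached 80.8%. Over its 8 alternatives the adjusted p ranged from 0.011 to 1 (exact or permutation).

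Of the 20 genes of the inhibitory interneuron list, 16 had a promoter peak in both replicates, which did not pass the test (80%, adjusted exact p = 0.13). Its strongest members had low signals: Adamts18 had 2.39 ± 0.240, Pvalb, a calcium buffer, 1.57 ± 0.305, Prkcd 1.38 ± 0.138 and Nxph1 1.15 ± 0.315 (SD, n = 2). Grm2, Htr2a and Slc6a5, the neuronal glycine transporter, had a peak in replicate 1 alone, and Ptf1a, a factor of early inhibitory progenitors, in neither. With replicate 1 alone 19 of the 20 genes had a peak and the list passed (adjusted exact p = 0.0066). With the stronger peaks of each replicate it lay below the other genes (adjusted exact p = 0.015), and over its 8 alternatives the adjusted p ranged up to 0.94 (exact or permutation). Nxph1 had 4.82 with a window of 2.5 kb.

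The lists of Bergmann glia and astrocytes and of the oligodendrocyte lineage did not pass the test. Bergmann glia and astrocyte genes had a promoter peak in both replicates for 15 of 25 (60%, adjusted exact p = 0.84), led by Etv5 at 14.8 ± 6.18 signal units, Id4 at 5.16 ± 1.505, Gli1, a Hedgehog pathway factor, at 4.82 ± 2.24 and Etv4 at 3.13 ± 0.699 (SD, n = 2). Within 500 bp Gli1 had 2.82. A2m had a peak in replicate 1 alone, Aldh1l1 and Fgfr3 in replicate 2 alone and Dao, a D-amino acid oxidase, in neither. Of 25 oligodendrocyte lineage genes 14 had one (56.0%, adjusted exact p = 0.57), led by St18 at 2.02 ± 0.696, Mbp, a myelin protein, at 1.48 ± 0.0879 and Myrf, a myelin regulator, at 1.32 ± 0.0891. Aspa, Cspg4, Ermn and Gpr17 had no promoter peak in either replicate. With the stronger peaks the oligodendrocyte list was below (adjusted exact p = 0.031, the lowest of 8 alternatives, with 1 the highest).

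Of the lists of other cell types, that of microglia passed, as below the rest. Of 22 microglia genes 3 had a promoter peak in both replicates (adjusted exact p = 1.3e-05), among them C1qc at 1.31 ± 0.508 and Irf8 at 1.10 in replicate 1 and 1.51 in replicate 2, in peaks that do not overlap. This call ended against genes matched on CpG ratio (adjusted permutation p = 0.38, the highest of its 8 alternatives, with 2.3e-06 the lowest). Endothelial and mural genes had 9 of 22 (adjusted exact p = 0.066), with Slc2a1, the glucose transporter of the blood-brain barrier, at 4.81 ± 1.05, Esam at 0.923 ± 0.0114, Mfsd2a at 0.729 ± 0.0927 and Flt1 at 0.501 ± 0.139. That list was below in 5 of 8 alternatives: 500 bp (adjusted exact p = 0.012), the stronger peaks (2.9e-05), equal numbers (2.1e-04), the shorter lists (0.0014) and without replicate 2 (0.032), with 0.23 the highest p. Choroid plexus and meningeal genes had 6 of 16 (adjusted exact p = 0.086), led by Col1a1, a collagen, at 4.19 ± 2.34, Otx2 at 1.37 ± 0.683 and Igfbp2 at 0.562 ± 0.0425, with Foxd1 at 0.345 in replicate 1 and 0.476 in replicate 2, in peaks that do not overlap. Without replicate 1 Col1a1 had 2.53 and Otx2 0.888. That list was below in 4 of 8 alternatives: 500 bp (adjusted exact p = 0.030), the stronger peaks (0.0011), equal numbers (0.0020) and the shorter lists (7.9e-04), with 0.67 the highest p. Forebrain genes had 10 of 22 (adjusted exact p = 0.14), with Ppp1r1b at 2.45 ± 0.498, Drd1, a dopamine receptor, at 2.13 ± 0.738 and Eomes at 1.49 in replicate 1 and 1.97 in replicate 2, in peaks that do not overlap. Against random lists matched on CpG ratio, at 88.5%, the forebrain list was below (adjusted permutation p = 9.0e-04, the lowest of its 8 alternatives, with 0.89 the highest), as it was with the stronger peaks (adjusted exact p = 0.014) and the shorter lists (0.021).

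HOX genes and lists of non-neural tissues had few promoter peaks. Of 39 HOX genes, which set position along the body axis in 4 gene clusters so that members are not independent, only Hoxa7 (3.17 ± 0.784) and Hoxc5 had a promoter peak in both replicates (5.13%, adjusted exact p = 1.1e-12). The Hoxc5 peaks, at 0.690 in replicate 1 and 0.462 in replicate 2, do not overlap. Liver genes had 3 of 24 (adjusted exact p = 4.1e-06): Apoh at 7.31 ± 0.219, whose peak also lay by a start site of Prkca, Apob at 1.11 ± 0.704 (0.613 without replicate 1) and Apoc3 at 0.736 ± 0.113. Striated muscle and heart genes had 3 of 23 (adjusted exact p = 7.1e-06), with 9 in replicate 1 and 3 in replicate 2, and with replicate 1 alone the list was still below (adjusted exact p = 0.023). The 3 were Actn3 at 7.53 ± 0.0241 and Mylpf at 5.58 ± 1.61, whose peaks also lay by start sites of Zdhhc24 and Tbc1d10b, and Mybpc3 at 4.28 ± 1.23. Lymphoid and erythroid genes had 5 of 23 (adjusted exact p = 2.1e-04), led by Rag1 at 2.70 ± 0.178, whose peak also lay by B230118H07Rik, Epor at 1.10 ± 0.346 and Tal1 at 0.838 ± 0.338. Pax5 had 1.02 in replicate 1 and 1.35 in replicate 2, in peaks that do not overlap. Of 21 germ cell genes only Dazl, an RNA-binding protein, had one (4.25 ± 1.41, adjusted exact p = 4.1e-07). The 8 Y-linked genes are a background check, since the labels give females, and 0 had a promoter peak. Matched on CpG ratio, the liver and the lymphoid and erythroid calls ended (adjusted permutation p = 0.50 and 1, each the highest of 8 alternatives, the lowest being 5.2e-07 and 7.1e-05). Within 500 bp Apoh had 4.03 and within 2.5 kb Mybpc3 had 8.13. With a window of 2.5 kb the muscle and heart call ended (adjusted exact p = 0.076, its lowest being 1.4e-07).

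All 25 housekeeping genes had a promoter peak in both replicates (adjusted exact p = 2.5e-05), led by Eef2, a translation factor, at 14.8 ± 1.33 signal units, Ppia at 14.6 ± 1.22, Vps29 at 14.4 ± 1.39, whose peak also lay by Rad9b, and Ywhaz at 13.4 ± 3.98 (SD, n = 2). All 21 immediate early genes, which respond to neuronal activity, did so too (adjusted exact p = 1.3e-04): Jun had 14.6 ± 1.59, Dusp1, a phosphatase, 14.1 ± 4.80, Jund 13.3 ± 4.33 and Egr1 12.97 ± 1.89. Of 19 GABA-A and NMDA receptor subunit genes 17 had one (89.5%, adjusted exact p = 0.026), with Grin2a at 5.25 ± 0.428, Grin1 at 4.33 ± 0.0201 and Grin2c at 3.40 ± 0.328. These 3 calls ended against genes matched on CpG ratio (adjusted permutation p = 0.55, 0.50 and 0.27, each the highest of 8 alternatives, the lowest being 2.2e-06, 1.7e-05 and 0.025). For the housekeeping and immediate early lists matched random lists averaged 93.5% and 92.5% and often reached 100%. At that ceiling neither list could have been called above, so this alternative decides nothing for them. The receptor call also ended with windows of 500 bp (adjusted exact p = 0.073) and 2.5 kb (0.051) and with the stronger peaks (0.12). Gabra6, Gabrd and Grin2c are on both the receptor and the granule cell list, so the results of these lists are not independent.

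**Figure D1:**
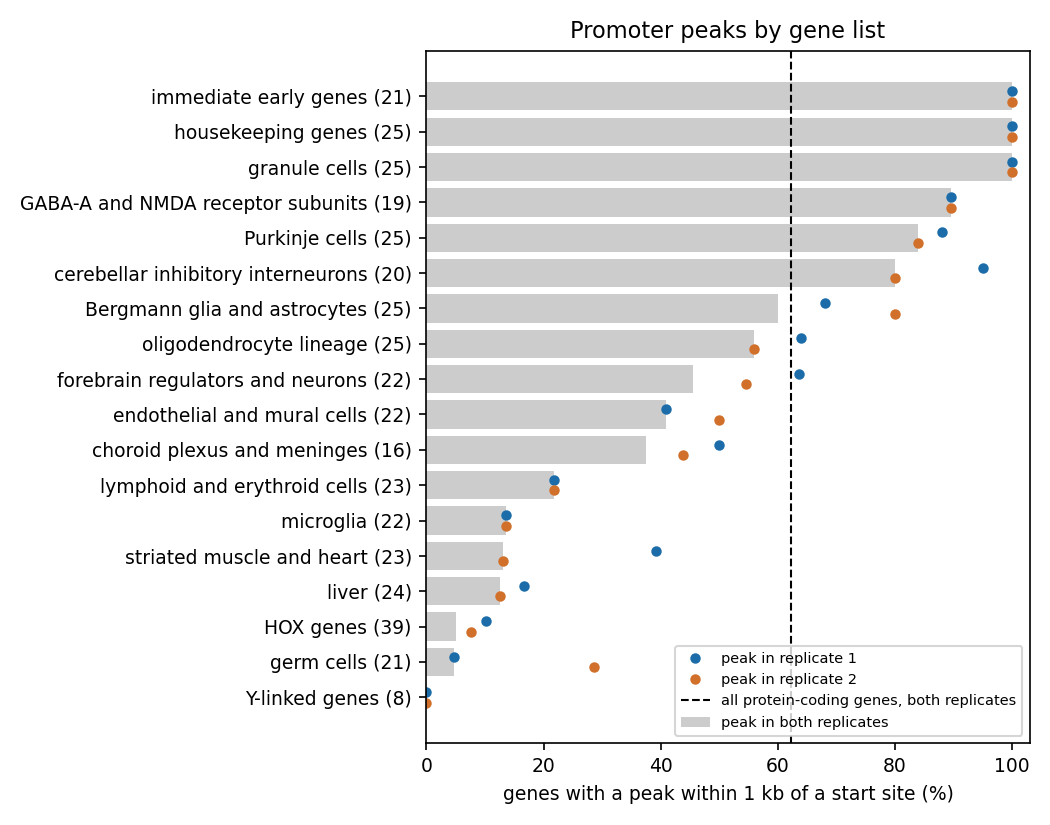
Share of the genes of each list with a peak within 1 kb of a start site (%); bars give both replicates, points each replicate, and the dashed line all protein-coding genes, with the number of genes in brackets. The granule, housekeeping and immediate early lists reached 100% and the Y-linked list 0%.

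In all, 13605 of 21853 protein-coding genes (62.3%) had an accessible promoter in both replicates. Replicate 1 alone had a promoter peak at 654 further genes and replicate 2 alone at 277. Start sites took 22.2% of the peaks of replicate 1 (95% Wilson interval 21.9 to 22.4) and 27.3% of those of replicate 2 (27.0 to 27.6), a mean of 24.7% ± 3.66 (SD, n = 2); intervals cover counting error only. Peaks shared by the animals lay at start sites more often than the others, 29.4% against 12.9% in replicate 1 and 29.1% against 18.97% in replicate 2 (odds ratios 2.81 and 1.75, p below 1e-300 and p = 2.1e-162, Fisher's exact test over peaks, two-sided). Peaks at start sites had a median of 1.19 signal units against 0.532 at distal peaks in replicate 1, and 1.85 against 0.686 in replicate 2.

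Distal peaks, over 1 kb from any protein-coding start site, were dense around granule cell genes. Granule genes had 33.0 ± 11.1 distal peaks within 100 kb per gene (SD over 2 replicates), 3.35 times the 9.85 of random lists matched on gene density (adjusted p = 0.0012, permutation with 10000 lists, whose unadjusted p of 2.0e-04 is the smallest possible). Tiam1 had 66 and 43 of them in replicates 1 and 2, Zic2 64 and 35, Neurod1 55 and 26 and Cbln3 21 and 9. Immediate early genes had 19.5 ± 3.94 against 10.95 (adjusted p = 0.0099) and Purkinje genes 17.5 ± 6.42 against 9.84 (adjusted p = 0.019, permutation). The Purkinje call ended without replicate 1 (1.65 times, adjusted permutation p = 0.073) and, in an alternative chosen after the data were seen, with only the most upstream start site of each gene (1.34 times, adjusted p = 0.23, the highest of its 9 alternatives, the lowest being 0.012). The immediate early call ended with distal peaks over 2.5 kb from any start site (1.59 times, adjusted permutation p = 0.055, the highest of 9, the lowest being 9.0e-04). With each peak given only to its nearest start site, the ratio was 5.27 for granule genes, 3.16 for immediate early genes and 0.175 for HOX genes. That of liver genes, which did not pass, went from 0.889 to 0.505 there.

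Around HOX genes there were 4.65 ± 2.01 distal peaks per gene against 10.8 in random lists (adjusted p = 0.0012, permutation). Y-linked genes, the background check in females, had 0.688 ± 0.619, or 0.0808 times the mean of random lists. That ratio was 0.0394 without replicate 1, 0.0190 with equal numbers of peaks and 0.0377 within 50 kb. The other 13 lists did not pass. Striated muscle and heart genes had 16.1 ± 3.44 against 11.4 (adjusted permutation p = 0.14), housekeeping genes 13.8 ± 3.03 against 11.1, microglia genes 13.4 ± 4.15 against 10.4 (both adjusted p = 0.42) and lymphoid and erythroid genes 12.98 ± 3.17 against 11.1 (adjusted p = 0.73). Bergmann glia and astrocyte genes had 11.1 ± 2.83 against 10.1, oligodendrocyte genes 10.9 ± 2.40 against 10.4, germ cell genes 10.2 ± 2.73 against 9.90 and receptor subunit genes 9.84 ± 4.24 against 9.46. Choroid plexus genes had 9.72 ± 2.96 against 9.49, endothelial genes 9.09 ± 3.34 against 10.1, liver genes 9.08 ± 3.65 against 10.2, forebrain genes 8.75 ± 3.05 against 8.82 and interneuron genes 7.28 ± 1.94 against 9.02, with adjusted p between 0.73 and 0.93.

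**Figure D2:**
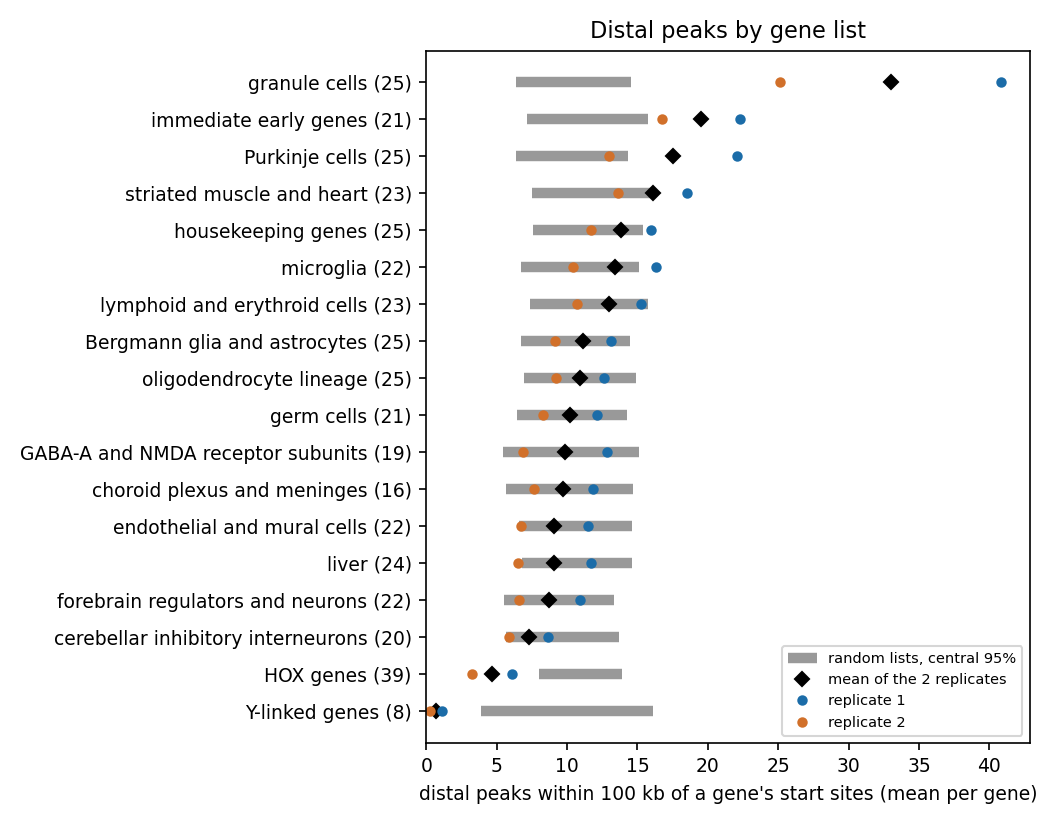
Mean number of distal peaks per gene within 100 kb of a list's start sites; diamonds are the mean of the 2 replicates, points each replicate, and grey lines the central 95% of 10000 random lists matched on gene density. Granule cell genes, at 33.0, lie above the 14.6 at the upper end of their line.

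The genes with the most distal peaks were Fgfr2 (247 and 159 in replicates 1 and 2), a fibroblast growth factor receptor, Ntm (125 and 118), a neural adhesion molecule, and Rbfox1 (135 and 97), a splicing factor. Rbfox3, also a splicing factor and the NeuN antigen, had 125 and 91, Kirrel3 106 and 88, Gse1 133 and 77 and Nrxn2, a presynaptic adhesion protein, 83 and 74. G430095P16Rik (94 and 89), Trmt1 (91 and 87) and Lyl1 (87 and 84) lie within 1 stretch of chromosome 8, from 84686339 to 84723007, so their counts overlap. The start sites of Fgfr2 span 2861 kb, those of Rbfox1 1468 kb and those of Ntm 949 kb, which widens the window counted. With only the most upstream start site, the mean count was 16 for Fgfr2, 4 for Ntm, 12 for Rbfox1, 45 for Rbfox3, 13.5 for Kirrel3, 33 for Gse1 and 31.5 for Nrxn2, and G430095P16Rik (94 and 89), Lyl1 (87 and 84), Nacc1 (72 and 75) and Slc22a12 (79 and 70) led. Nacc1, at 84687862, starts within the same stretch of chromosome 8, so its count overlaps those of G430095P16Rik and Lyl1. The window of Slc22a12, which starts at 6543032 on chromosome 19, overlaps that of Nrxn2. Within 50 kb the mean counts were 34 for G430095P16Rik and Trmt1, 31.5 for Lyl1 and 50.5 for Nrxn2. With each peak given only to its nearest start site they were 67.5 for Gse1, 49.5 for Ntm, 31 for Kirrel3, 26.5 for Nrxn2, 7.5 for G430095P16Rik, 6.5 for Fgfr2 and Lyl1 and 3 for Trmt1. With the stronger peaks they were 111.5 for Fgfr2, 67.5 for Ntm, 61 for Rbfox1, 59.5 for G430095P16Rik, 58 for Trmt1, 54.5 for Lyl1, 47.5 for Kirrel3 and 40.5 for Nrxn2.

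Of the 10 strongest distal peaks, the first lay on chromosome 17 at 39846781 to 39846900, 104 kb from Esp38, with 46.2 signal units in replicate 1 and 59.9 in replicate 2. The next lay on chromosome 9 at 123461901 to 123462100 in an untranslated region of Lars2 (37.2 and 29.7), 16.7 kb from the start site of Limd1, and on chromosome 3 at 5860361 to 5860530 in intergenic sequence 110 kb from Gm8797 (21.6 and 27.3). Intergenic sites on chromosome 8 at 20424741 to 20424940 (31.2 and 23.0, nearest Gm15319) and at 20122141 to 20122300 (25.0 and 22.7, nearest Gm31371), and on chromosome 7 at 34234101 to 34234340 (16.2 and 22.5, 3.89 kb from Gpi1), were also among them. The others lay in introns of Il31ra (chromosome 13, 112578161 to 112578320, 21.9 and 23.5), Vps37c (chromosome 19, 10709481 to 10709660, 25.0 and 22.6, nearest Cd5) and Zc3h7a (chromosome 16, 11144171 to 11144320, 16.8 and 27.2, nearest Txndc11), and in an untranslated region of Cers5 (chromosome 15, 99735661 to 99736060, 25.9 and 22.7, nearest Cox14). Intergenic means outside protein-coding genes only. The peak lists were not filtered here for multi-copy or poorly mappable sequence. How far such sequence raised these strongest signals was not checked.

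The animals shared most of their strong sites. Of the peaks of replicate 1, 78298 (55.9%, 95% Wilson interval 55.6 to 56.2) overlapped a peak of replicate 2 by at least 1 bp, and of those of replicate 2, 78092 (82.7%, 82.5 to 82.9) overlapped a peak of replicate 1. Shifted positions gave 1.60% and 2.35% (one-sided permutation p = 0.0099 with 100 shifts, the smallest possible). With equal numbers of peaks the shares were 73.5% in replicate 1 and 73.7% in replicate 2. The shared share rose from 11.1% in the weakest decile of replicate 1 to 99.3% in the strongest, and from 36.9% to 99.4% in replicate 2. Across the 78298 pairs, which are not independent replicates, the signals had a Pearson r of 0.896 and a Spearman rho of 0.880, and 86.5% of pairs lay within 2-fold.

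**Figure D3:**
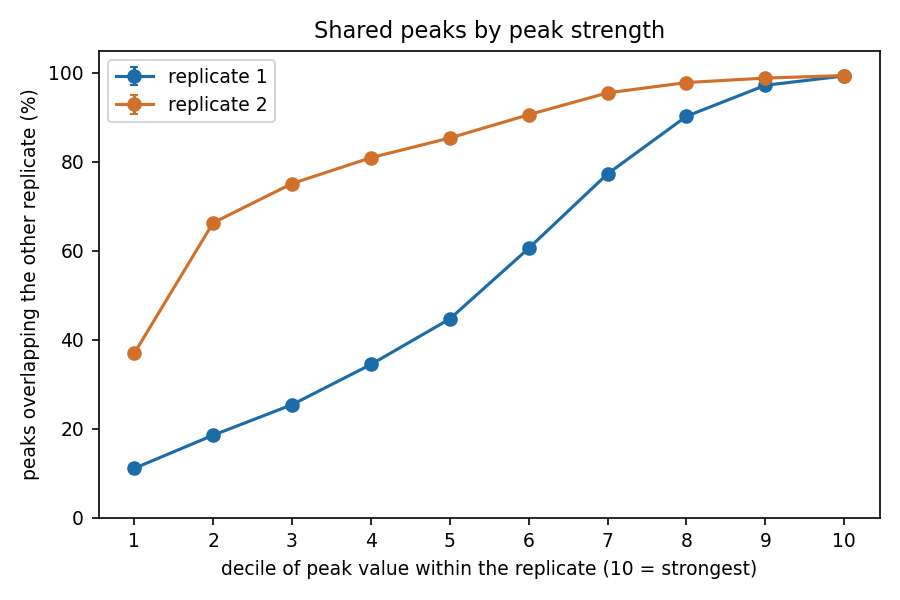
Share of peaks that overlap a peak of the other replicate (%) by decile of signal within the replicate, 10 being the strongest, with 95% Wilson intervals. Both curves rise, to 99.3% in replicate 1 and 99.4% in replicate 2.

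The strongest peaks without an overlap in the other animal lay close to its peaks. In replicate 1 they lay at the start sites of Fntb (chromosome 12, 76837301 to 76837560, 9.84 signal units) and Scamp1 (chromosome 13, 94285721 to 94285900, 8.69), near Pop7 (chromosome 5, 137502061 to 137502320, 8.47), and at a pair of intergenic sites about 10 kb from Tmpo (chromosome 10, 91181401 to 91181620 and 91181981 to 91182220, 9.51 and 8.77). The nearest peak of replicate 2 was 20 to 80 bp away from each. In replicate 2 they lay in an intron of Mid1 (chromosome X, 169998241 to 169998420, 11.1) and at Rhbdd3 (chromosome 11, 5099241 to 5099460, 10.6), Psme3 (chromosome 11, 101316081 to 101316280, 10.4) and Plekhj1 (chromosome 10, 80798421 to 80798740, 10.4). A peak of replicate 1 adjoined each of these 4 with a gap of 0 bp.

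Consensus sites of the insulator protein CTCF marked peaks most of all. CTCF sites were 108 ± 16.2 times as frequent in the central 150 bp of peaks as in windows 1 kb away (SD, n = 2; present in 4.32% of peaks), and the palindromic nuclear factor I site 23.9 ± 1.15 times. NRF1 followed at 18.3 ± 0.113, YY1 at 15.5 ± 1.34, REST, a repressor of neuronal genes, at 9.42 ± 0.0528, CRE, the CREB site, at 8.07 ± 1.95, ETS at 6.70 ± 0.941 and SP/KLF at 5.43 ± 1.21. ZIC sites were 3.003 ± 0.184 times and MYOD E-box sites 2.26 ± 0.286 times as frequent. In all, 18 of 30 consensus sites were above their flanks in both replicates and 6 below (adjusted p at most 0.0065 in each replicate, Fisher's exact test over windows). Below were the homeodomain site TAATTA at 0.399 ± 0.0752, GATA at 0.423 ± 0.117, OTX at 0.533 ± 0.0698, POU at 0.615 ± 0.0722, TEAD at 0.843 ± 0.0673 and SOX at 0.874 ± 0.0350.

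The sites that did not pass in both replicates were HNF4 (0.858 ± 0.0303, larger adjusted exact p = 0.12), PU.1 (1.13 ± 0.544, 0.43), the SOX dimer (1.39 ± 0.622, 1), HNF1 and p53, which had no site in any peak window, and MEF2. PU.1 sites were in only 16 and 15 peak windows and HNF1 sites in 2 and 1 flanking windows, so the test had little reach for them. EBF sites passed as above their flanks, at 1.52 ± 0.145 (SD, n = 2). MEF2 sites, bound by activity-dependent neuronal factors, had a ratio of 1.21 in replicate 1, which passed, and 1.15 in replicate 2, which did not (adjusted exact p = 0.094). Against windows of matched GC content MEF2 sites were 4.69 ± 0.801 times as frequent (larger adjusted exact p = 3.6e-39, the lowest of 6 alternatives, with 0.99 the highest). Under the same control TAATTA (1.66 ± 0.0282), POU (1.45 ± 0.226) and TEAD (1.23 ± 0.0546) lay above 1, so the direction of these 3 turned, while NFY, MYOD E-box, EBF, SOX and GATA sites no longer passed. The ratio was 63.9 for CTCF, 8.18 for NRF1, 8.60 for YY1, 3.54 for CRE, 3.62 for ETS, 1.64 for SP/KLF and 1.76 for ZIC there. REST sites had 16.7 in replicate 1 and 3 in replicate 2 under that control. Among distal peaks alone NRF1 had 4.56, YY1 2.79, CRE 3.80, ETS 1.95 and SP/KLF 2.07, and TEAD no longer passed. With the stronger peaks NRF1 had 29.9, YY1 23.3, CRE 13.4, ETS 10.4 and the palindromic NFI site 15.6, and in 100 bp windows REST had 15.3. MEF2 also passed in distal peaks (1.45) and with the stronger peaks (1.31).

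**Figure D4:**
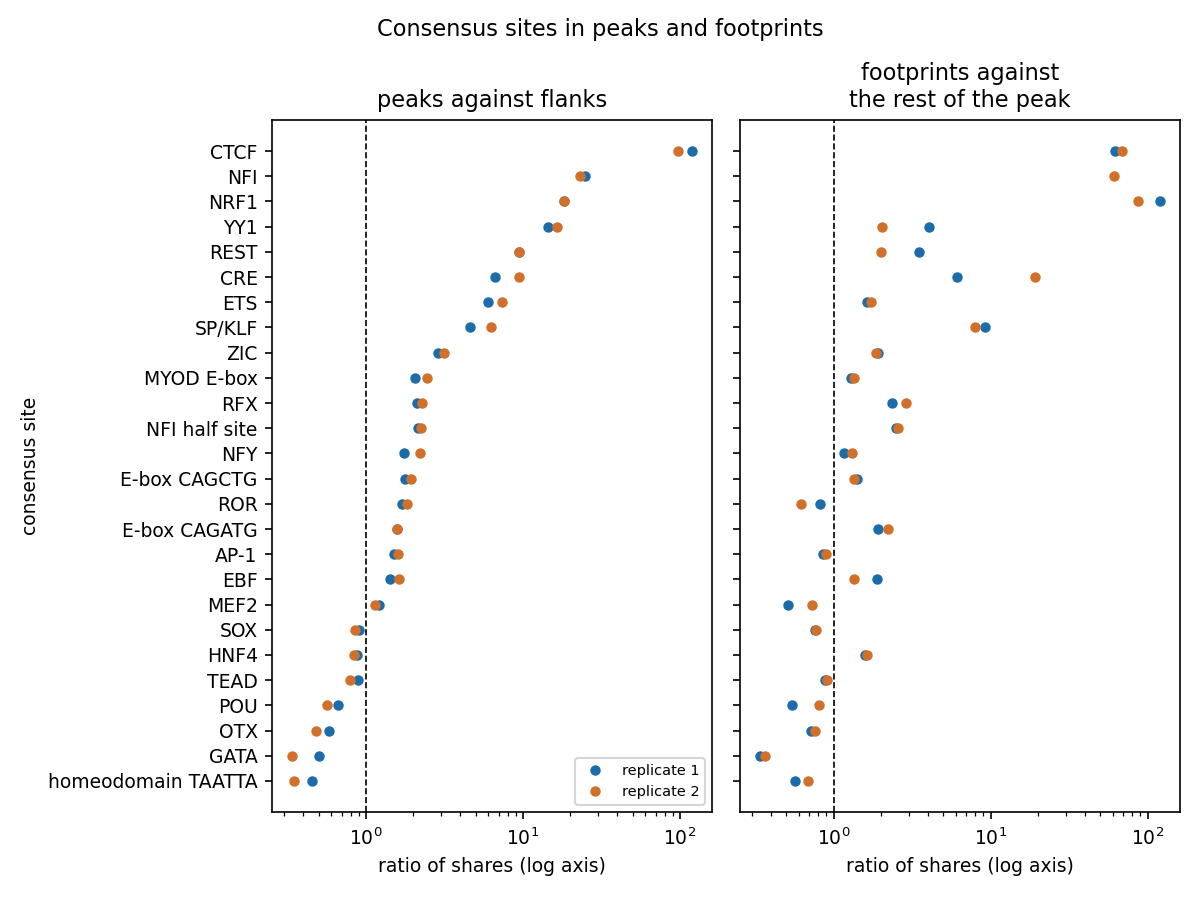
Ratio of the share of windows with each consensus site on log axes, in peaks against flanks (left) and in footprints against the rest of the peak (right), with 1 point per replicate; the 26 of 30 sites present in over 0.02% of peak windows are drawn. CTCF lies at 108 in peaks and 65.1 in footprints on average, and the NFI point of replicate 1 is absent from the right panel because its control count was 0.

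Footprints are short stretches protected from cutting inside open chromatin, where a protein is bound in the usual reading of the assay. The authors' lists held 462909 footprints in replicate 1 and 272138 in replicate 2, with a median width of 10 bp. Of these 78.0% and 81.0% lay fully inside a peak. Footprints overlapped one of the other animal for 35.2% in replicate 1 (95% Wilson interval 35.1 to 35.3) and 63.1% in replicate 2 (62.9 to 63.3), and for 41.4% in replicate 2 with reciprocal overlap of 50%. Inside peaks the shares were 36.1% and 64.4%, against 24.9% and 42.5% when footprints were shifted within their peaks (one-sided permutation p = 0.0099, the smallest possible with 100 shifts).

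CTCF sites were 65.1 ± 4.55 times as frequent in footprints as in the rest of the same peaks (SD, n = 2). NRF1 sites were 103.4 ± 22.7 times as frequent, but in only 2 and 3 control windows, so that the 95% interval was 29.7 to 481 in replicate 1 and 28.0 to 273 in replicate 2. The palindromic NFI site was in 124 footprints of replicate 1 and none of their controls, a ratio of at least 41.3 at a floor of 3 counts over the control windows, and had a ratio of 61.0 in replicate 2 (95% interval 8.46 to 440). CRE followed at 12.7 ± 9.28, SP/KLF at 8.57 ± 0.944, YY1 at 3.05 ± 1.43, RFX at 2.61 ± 0.368, the single NFI arm at 2.55 ± 0.0580, the NeuroD-type E-box CAGATG at 2.07 ± 0.209 and ZIC at 1.90 ± 0.0355. In all, 15 of 30 sites were above in both replicates and 6 below (AP-1, ROR, SOX, OTX, TAATTA and GATA, the last at 0.351 ± 0.0177). The control windows of footprints were not matched on GC content, so the part of base composition in these ratios was not checked. With footprints widened by 10 bp per side the ratio was 50.25 for NRF1, 34.4 for CTCF, 6.36 for CRE, 4.90 for SP/KLF and 1.92 for YY1, and with none it was 639.6 for CTCF, 59.7 for CRE, 20.1 for SP/KLF, 4.44 for RFX, 3.82 for the single NFI arm and 2.86 for ZIC. With none NRF1 had no ratio in 1 replicate, AP-1 had 0.535, OTX 0.470, SOX 0.464, ROR 0.392 and TAATTA 0.385, and MEF2 (0.295, adjusted exact p = 0.026) and POU (0.332, adjusted exact p = 1.4e-04) passed as below. The CRE ratio was 6.13 without replicate 2 and 19.3 without replicate 1. In distal peaks NRF1 had 53.5 and CRE 6.62, and the calls of YY1 (7.67, adjusted exact p = 0.14) and ETS ended. The AP-1 call ended at 10 bp and in distal peaks, those of MYOD E-box and EBF at 10 bp, and those of NFY and MYOD E-box with no widening. REST, HNF4, MEF2, POU, TEAD, PU.1, the SOX dimer, HNF1 and p53 did not pass in both.

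The X chromosome had fewer peaks per Mb than the autosomes, with 21.03 against 55.4 in replicate 1 and 14.7 against 37.3 in replicate 2. The Y chromosome, which these females lack by the labels, had 48 peaks in replicate 1 and 35 in replicate 2, or 0.523 and 0.381 per Mb. Of these 16 and 20 lay in its last 2 Mb, and the rest had a median of 0.0790 and 0.0938 signal units. No Y-linked gene of the list had a promoter peak in either replicate. Xist, the RNA gene of X inactivation, chosen after the data were seen, had a peak within 1 kb of a start site in both, at 1.69 and 0.953 signal units, but these peaks do not overlap (103484141 to 103484340 in replicate 1, 103481901 to 103482380 in replicate 2). No test was made of these densities.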

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

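Bases at an FDR of 0.05 or less lay outside every peak of the longer list for 45.0% of their length in replicate 1 and 43.5% in replicate 2. They stand out because the comparisons of genes, sites and animals rest on the peak and footprint lists, while the FDR file served only to describe those lists, and they amount to 25.1 and 15.7 Mb. At an FDR of 0.001 or less the shares were 44.0% and 42.8%.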

How the results depend on the processing

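The distal alternative with only the most upstream start site was chosen after the data were seen; the others were planned. The count of genes with an accessible promoter stayed within 1.5 times under its 7 alternatives, and the shared shares of peaks and footprints stayed above those of shifted positions under theirs. A stricter set and equal numbers of footprints could not be run, since their score is constant, and no ratio exists where a control count was 0 (the palindromic NFI site, the SOX dimer, HNF1 and p53 in footprints, NRF1 and PU.1 there with no widening, p53 in peaks and HNF1 there with GC-matched windows). The cause of the changes below was not tested. Pearson r was 0.893 with reciprocal overlap, 0.871 with the stronger peaks and 0.904 on a log scale, and rho 0.825 with the stronger peaks. The mean share of peaks near start sites was 19.5% at 500 bp, 31.4% at 2.5 kb, 34.7% with the stronger peaks and 31.3% with the shorter lists. Of the 5 gene lists above in promoter peaks, 3 were counted at 2.5 kb, 3 with the stronger peaks and 1 with CpG matching; with the stronger peaks 12 lists were below in place of 7, the Y-linked background check included. With GC-matched windows 1 consensus site was below in place of 6. With the stronger peaks and the shorter lists the mean peaks per Mb were 23.2 and 29.997 on autosomes, 6.60 and 10.9 on X, and 0.0926 and 0.251 on Y.

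The promoter difference of interneuron genes turned to -29.9 percentage points with the stronger peaks, -9.46 with equal numbers, -18.2 with the shorter lists and -4.67 with CpG matching. That of Bergmann glia and astrocyte genes turned to 7.19 at 2.5 kb, 1.79 with CpG matching and 2.75 to 16.5 with each replicate left out. Distal ratios crossed 1 only for lists that did not pass. With the stronger peaks they were 0.968 for Bergmann glia and astrocytes, 0.970 for oligodendrocytes, 0.931 for choroid plexus and 1.11 for forebrain. With the nearest start site only they were 1.04 for interneurons, 0.614 for microglia, 1.03 for forebrain, 0.704 for lymphoid and erythroid cells and 0.521 for germ cells. Within 50 kb they were 0.983 for microglia, 0.968 for choroid plexus, 1.07 for forebrain, 0.922 for germ cells and 0.892 for receptor subunits. With no matching they were 0.915 for choroid plexus, 0.964 for germ cells and 0.927 for receptor subunits, and with equal numbers 0.983 for choroid plexus and 1.04 for forebrain. Forebrain genes had 1.004 over 2.5 kb from start sites and 1.16 with the most upstream start site, and receptor subunits 0.912 to 1.13 with each replicate left out.

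With GC-matched windows the ratio in peaks was 1.66 for TAATTA, 1.15 for HNF4, 0.914 for EBF, 1.23 for TEAD and 1.45 for POU. The SOX dimer had 0.894 and PU.1 0.889 in 100 bp windows, PU.1 0.779 with the stronger peaks, and with each replicate left out they had 0.955 to 1.83 and 0.749 to 1.52. In footprints, widening by 10 bp gave 1.06 for MEF2 and 1.04 for AP-1, and no widening gave 0.992 for MYOD E-box sites. NRF1 in footprints has wide counting intervals, from 2 and 3 control windows.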

Other observations

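The gene families, the comparison of start-site with distal peaks and the genes with a peak in 1 replicate were chosen after the data were seen, as were the tests on start-site peaks, on weak sites and on the OTX site. Sensory receptor families had few promoter peaks in cerebellum: 12 of 1134 olfactory receptor genes (1.06%) had a promoter peak in both replicates and 1 of 329 vomeronasal receptor genes did (adjusted exact p = 2.2e-138 for the latter, over 8 families). The test takes the genes of a family as independent, and no background matched on CpG ratio was used for the families. Of the defensin genes 1 of 64 had one and of the keratin-associated protein genes 3 of 57. Ribosomal protein genes had 76 of 79 (adjusted exact p = 2.5e-12) and Zfp zinc finger genes 342 of 394 (86.8%, adjusted exact p = 3.9e-27). Potassium channel genes, with 66 of 93, did not pass (adjusted exact p = 0.087). In the protocadherin gamma cluster 6 of 21 genes had a peak in both replicates (adjusted exact p = 0.0028), with 19 in replicate 1 and 6 in replicate 2.

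Many consensus sites differed in frequency between shared peaks at start sites and distal shared peaks. YY1 sites were 19 times, ETS sites 13.99 times, NRF1 sites 12.03 times, SP/KLF sites 11.1 times and CRE sites 6.07 times as frequent at start sites. CTCF sites, at a ratio of 0.158, ROR at 0.219, CAGATG at 0.305, MEF2 at 0.355 and ZIC at 0.484, were less frequent there. RFX (1.04, adjusted exact p = 0.49) and POU (0.946, adjusted exact p = 0.68) did not pass. GC content was not matched here, and 6772 of the 7829 shared peaks in the decile of highest GC content lay at start sites. Of the striated muscle and heart genes, 6 had a promoter peak in replicate 1 alone and 0 in replicate 2 alone: Tnni3 (1.25 signal units), Acta1 (0.982), Tnnt3 (0.896), Myl2 (0.656), Tnni2 (0.608) and Nkx2-5 (0.421). Of the germ cell genes, 5 had one in replicate 2 alone and 0 in replicate 1 alone: Tnp2 (0.469), Ddx4 (0.433), Sycp3 (0.375), Mael (0.310) and Piwil1 (0.289). With equal numbers of peaks these counts were again 6 and 5. Other lists moved in that setting: peaks in replicate 1 alone and replicate 2 alone went from 3 and 0 to 2 and 6 for interneurons, from 2 and 5 to 0 and 9 for Bergmann glia and astrocytes, and from 0 and 2 to 0 and 7 for endothelial and mural genes. None of these counts was tested.

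Shared peaks at start sites had a lower ratio of signal in replicate 1 to replicate 2 than distal shared peaks. The median log2 ratio of replicate 1 to replicate 2 was -0.26 at start sites and 0.14 at distal peaks, a difference of -0.40 (bootstrap SD 0.0057, 78298 pairs). It ran from 0.60 in the decile of lowest GC content to -0.44 in the highest, and with the median of each decile removed the difference was -0.0575, so a GC bias between the libraries may account for most of it. The decile medians include the start-site pairs, 6772 of 7829 in the highest decile. Removing them therefore also takes out part of any effect of start sites. Peak strength was not held fixed. A difference of promoters apart from GC content stayed open, since the mean difference within deciles was -0.12 (SD 0.0067), under 0.5 of the whole but not within 0.1 of 0. The design has 1 group, so no biological explanation was tested.

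Peaks called in replicate 1 alone numbered 61760. The list of replicate 1 was the longer, with 140058 peaks against 94426, which alone leaves many without a partner. With equal numbers of peaks 73.5% and 73.7% were shared in replicates 1 and 2. Noise as the whole cause of the peaks in replicate 1 alone is argued against by CTCF sites. These were 105.2 times as frequent in them as in their flanks (95% interval 72.9 to 152). At matched strength their median GC content was lower, by -3.61 percentage points (bootstrap SD 0.101), as a GC bias between the libraries would give. Position was not matched, though. Of these peaks 12.9% lay at start sites, against 29.4% of the shared peaks of replicate 1. Start sites held 6772 of the 7829 shared peaks of highest GC content. A GC bias was therefore not told apart from a smaller part of start-site peaks. Weak sites below the reach of the shallower library stay open: the signals of 97.3% lay below the median of shared peaks, but sharing was known to rise with strength and noise calls would be weak too, so this share decides nothing. No biological explanation was tested.

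6 consensus sites, AT-rich ones such as TAATTA among them, were below their flanks in peaks. Not all AT-rich sites were: MEF2 had 1.21 in replicate 1, which passed as above, and 1.15 in replicate 2. Against GC-matched windows 4 of the 6 had a ratio of 0.9 or more in both replicates, so the base composition of peaks may account for these. GATA sites had 0.958 in replicate 1 and 0.660 in replicate 2, which leaves them open. OTX sites stayed at 0.750 ± 0.010 (SD, n = 2), which GC content as the whole cause does not give. The GC-matched windows were not matched on repeat content or place in the genome. Such differences from the peaks therefore stay open as a cause of the low OTX ratio. No biological explanation was tested. A separate hypothesis, that distal peaks near granule cell genes hold more ZIC, NFI and NeuroD-type sites than other distal peaks, gave a negative result: 0 of the 3 sites were more frequent in both replicates. The single NFI arm was less frequent in replicate 1 (31.9% against 38.8%, adjusted exact p = 2.9e-05) but not in replicate 2 (41.5% against 42.4%, adjusted exact p = 0.68). GC content was not matched. The other distal peaks come from the same whole tissue and can include sites open in granule cells. The comparison therefore does not tell whether sites open in granule cells hold these sequences.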
